A study of Rattus norvegicus with 8 samples.

How the data were processed

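The study compared adrenal glands of neonatal rats kept from birth to postnatal day 7 in 12% O2 with glands of pups kept in room air. Per the labels, the glands were decapsulated, frozen and pooled with 24 glands per sample, and 4 pools per group were made into biotin-labelled cRNA. Each pool was hybridised to 1 array with 1 colour. The labels give the pools as separate samples of a group, so the spread between arrays holds the spread between pools as well as that of the assay. How litters were spread over the pools is not given in the sources used here.

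The deposited table holds probe set intensity values on a linear scale in arbitrary units, and per the labels each column is a pool. The software that summarised the probes is not given in the sources used here. In the values themselves, the mean of each array after trimming 2% at each end was the same to within rounding of the deposited intensity (500.1), so the authors' values had been scaled to a common mean. Such scaling sets the total signal of every array equal, and a change shared by most transcripts could not be seen. The table held 15923 probe sets with values from 0.0 to 30856.6, of which 2 values were exactly 0 and 233 were below 1. The table gave no detection calls, so 27 probe sets for bacterial genes served as background, with a median of 5.4, a 95th percentile of 46.7 and a highest value of 83.5. No 2 arrays had identical values: at most 0.303% of probe sets had equal values on a pair of arrays, and correlations between arrays over probe sets ran from 0.952 to 0.979.

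Gene names came from the platform's annotation, which can be old. After 57 control probe sets were left out, 12783 of 15866 probe sets had 1 gene symbol, 312 had several and 2771 had none in the table used. Of these, 12754 matched a gene ID in the RefSeq gene table of rat assembly GRCr8, and 0 symbols needed an update. The named probe sets stood for 10411 genes. No gene was named from a probe set with several symbols, which leaves out several members of the Cyp11b, Hsd3b and haemoglobin families. Cyp11b2 and Mc2r had no probe set named for them alone and are not analysed here. No coordinates are given, since the array's genome build is not given in the sources used here.

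Values below 1 were set to 1, 16 was added and log2 was taken. All fold changes are on this scale, which understates the change of dim probe sets. The array medians lay within 0.117 of each other on the log2 scale, under the limit of 0.2 set before, so the values were used as deposited with no further normalization. Probe sets whose mean log2 value over the 8 arrays lay below the 30th percentile (a signal of 95.2) were left out, which kept 11106 probe sets and 8011 named genes. Hypoxic and normoxic pools were compared with limma 3.58.1 (lmFit, and eBayes with a variance trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Means and SDs are of the deposited intensities over 4 pools. The smallest p that an exact permutation test of 4 against 4 can give is 0.0286. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

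Gene lists were written down before the data were examined, as were the tests, the alternatives and the rule for named genes. There were 6 lists on adrenal function and hypoxia, 8 lists of markers of cells that the dissected gland could hold besides inner cortex and medulla, and 10 lists of processes. Some genes stand in more than 1 list. A gene was represented by its tested probe set with the highest mean, and lists with at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, adjusted over 24 lists. Of these, 5 passed (3 higher and 2 lower), and 0 passed with a correlation estimated from the data, where the smallest adjusted p was 0.437, or by fry, which asks whether the genes of a list move on balance to 1 side. Every list was also adjusted on its own members. The genes named are up to 12 with the largest change in each direction among those past the threshold with no overlap between groups, at the brightest probe set of the gene. To these were added a fixed panel of adrenal and hypoxia genes, and up to 4 genes with the lowest p of each list.

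The same steps were tested on simulated data with the spread of the real probe sets. For the hypoxic against normoxic comparison on 11106 probe sets, 49% of 100 changed by 0.6 log2 and 82% of 100 changed by 1 log2 were recovered. There were 137 calls, 6 of them false, and 0 had the wrong sign. The adjustment is stricter where fewer probe sets change. The real comparison gave 20 calls, so these percentages may overstate what it could recover. Of the lists, 0 were called with no change simulated and glycolysis was called when its genes were raised by 0.3 log2. Every probe set was simulated independently of the others. In the real pools genes of a list varied together, with a mean residual correlation of 0.256 for chromaffin and 0.153 for glycolysis genes. The simulation therefore does not show how often lists are called falsely in the real data.

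The alternatives set beforehand were an offset of 1 or 64, no brightness filter or the 50th percentile, quantile normalization, subtraction of array medians, no variance trend, array weights, the replicate number as a block, each array left out, an unmoderated two-sample test, and thresholds of 1.5-fold or 0.1. For lists they were an estimated correlation, fry, and probe sets averaged per gene. After the data were seen, the log2 5' over 3' ratios of beta-actin and of Gapdh and the mean of the adipose genes were added as covariates, fits without both replicate 1 arrays were made because these had the lowest beta-actin ratio of their groups, and subtraction of array medians was extended to the lists. The follow-up measurements by real-time PCR that the design mentions are not analysed here.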

Results

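Gene expression was measured in the adrenal glands of rat pups on postnatal day 7. The pups had been kept with their dams from birth either in an atmosphere of 12% O2 or in room air. The gland makes steroid hormones in its cortex and catecholamines in the chromaffin cells of its medulla, and the outer capsule had been stripped off before RNA was extracted. There were 4 hypoxic and 4 normoxic samples, each a pool of 24 glands read on its own 1-colour oligonucleotide array. The values are probe set intensities in arbitrary units. The array medians lay between 228.6 and 249.2 after the authors' scaling to a common mean, which hides how bright the arrays were before it. Bacterial control probe sets, which match no rat transcript, had a median of 5.4 and a 95th percentile of 46.7. The number of arrays limits the precision of every value given here.

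The first comparison asked which transcripts differ between glands of hypoxic and normoxic pups. A small set of genes rose in the hypoxic glands. Slc18a2, the transporter that loads catecholamines into secretory vesicles, rose from 247.5 ± 44.5 to 502.9 ± 60.8 (SD, n = 4 pools each), a log2 change of 0.98 with a standard error of 0.14 (limma, adjusted p = 0.0318). Nefh, the heavy neurofilament chain, had the highest fold, 2.35, from 100.4 ± 18.2 to 260.2 ± 61.1. Cyp1b1, a cytochrome P450 that was abundant in these glands, rose from 4421 ± 883 to 7644 ± 391, a log2 change of 0.81. Gaa, the lysosomal enzyme that breaks down glycogen, rose from 903 ± 53.3 to 1538 ± 173 (log2 0.75), and Vnn1, a pantetheinase, from 1331 ± 136 to 2202 ± 264 (log2 0.72). The transcription factor gene Hhex rose from 255 ± 4.10 to 468 ± 54.4 (log2 0.83). The remaining named genes that rose were Fxyd5, a regulator of the sodium pump (log2 0.85), Tmem119 (0.81), Ttc39a (0.73), the protease inhibitor Spint2 (0.64), the extracellular glycoprotein gene Reln (0.61) and Atxn10 (0.60). Slc7a1, a transporter of arginine and other cationic amino acids, passed at a dimmer probe set (log2 0.66, adjusted p = 0.0318) but not at its brightest probe set (log2 0.34, adjusted p = 0.392).

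Fewer genes fell. Cdh1, which encodes the adhesion protein E-cadherin, fell from 1345 ± 175 to 639 ± 167 (n = 4 pools each), a log2 change of -1.08 with a standard error of 0.17 (limma, adjusted p = 0.0325). Normoxic pool 4, at 1087, lay apart from the other normoxic pools for this gene. Pimreg, a gene of mitosis, fell from 1272 ± 249 to 642 ± 47.9 (log2 -0.95). Pla2g4a, the phospholipase that releases arachidonic acid, fell from 1143 ± 106 to 626 ± 103 (log2 -0.86). Bcan, which encodes the proteoglycan brevican, fell from 877 ± 170 to 486 ± 31.3 (log2 -0.81). Aox1, an aldehyde oxidase, fell from 1955 ± 179 to 1200.5 ± 157 (log2 -0.70), and the centromere protein gene Itgb3bp fell from 583 ± 35.2 to 369 ± 36.8 (log2 -0.64).

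In all, 20 of 11106 probe sets passed an adjusted p of 0.05 in limma, 13 higher and 7 lower in hypoxic glands, with folds from 1.52 to 2.35. They stood for 13 named genes that rose and 6 that fell, and 1 lower probe set had no gene name in the table used. For all 20 probe sets the 4 hypoxic values lay on 1 side of the 4 normoxic values. Over all tested probe sets 5.39% were separated in this way, where chance gives 2.86%, and 960 probe sets (8.64%) had an unadjusted p under 0.05. Of the other ways to split the 8 arrays into 4 and 4, 2 gave more such probe sets, 1282 and 1156. Where a gene had a second probe set, Reln was also higher on it (log2 0.66, adjusted p = 0.234), Slc18a2 was higher by less (log2 0.61, adjusted p = 0.399) and Bcan was lower by less (log2 -0.30, adjusted p = 0.746). The count was 0 without normoxic pool 1, 2 or 3 or hypoxic pool 2 or 3, 1 without normoxic pool 4, 2 without hypoxic pool 4 and 31 without hypoxic pool 1. It was also 0 with no brightness filter (smallest adjusted p 0.0575 in limma) and with no variance trend (0.0770). With the Gapdh 5' over 3' ratio as a covariate it was 0 too (0.0981), and each of the 20 kept its direction there. The filter and trend settings leave the log2 changes as they were, so no direction could turn in them.

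**Figure D1:**
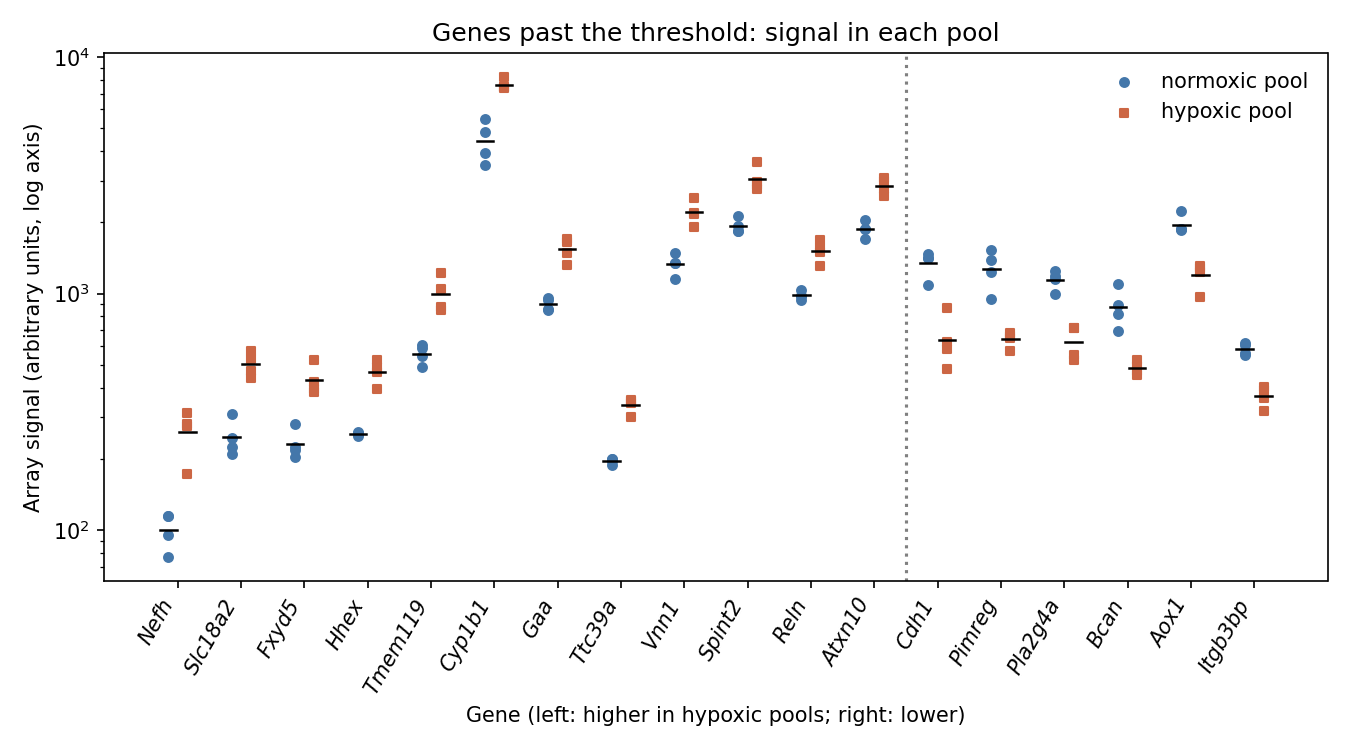
Signal of each pool (arbitrary units, log axis) for the 18 genes that passed the threshold at their brightest probe set; circles are normoxic pools, squares hypoxic pools and bars group means (n = 4 each). Nefh signals lie between 76.7 and 114.8 in normoxic pools and between 172.1 and 313.4 in hypoxic pools, and Cdh1 signals fall from a mean of 1345 to 639.

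The design named genes of adrenal function as a question of their own, and the steroid-producing pathway showed no detectable change in these pools. Star, which carries cholesterol into the mitochondrion, measured 11902 ± 1702 in normoxic and 11761 ± 1420 in hypoxic glands (n = 4 pools each), a log2 difference of -0.01 with a 95% interval from -0.29 to 0.26, and its second probe set differed by 0.09. The side-chain cleavage enzyme gene Cyp11a1 differed by 0.09 (interval -0.21 to 0.39), the 21-hydroxylase gene Cyp21a1 by 0.03 (interval -0.39 to 0.45) and the 11-beta-hydroxylase gene Cyp11b1 by 0.06 (interval -0.29 to 0.41). Hsd3b1 and the electron donor gene Fdx1 each differed by 0.01. Among the 19 measured genes of the list, 0 passed limma adjusted over all probe sets and 0 when adjusted over the list alone, while 3 had an unadjusted p under 0.05, all of them lower in hypoxic glands. These were Hsd11b2, which inactivates corticosterone (log2 -0.52, adjusted p = 0.371), Akr1c3 (log2 -0.27, adjusted p = 0.468) and the nuclear receptor gene Nr0b1 (log2 -0.23, adjusted p = 0.533). Dbi, the acyl-CoA binding protein gene, had a log2 difference of -0.33 and the transcription factor gene Nr5a1 one of -0.27, with hypoxic pool 1, at 364, far below the other hypoxic pools. The list did not move as a group (camera adjusted p = 0.789); its median was 0.03, while its mean of -0.02 and the test leaned lower. The sign of the small differences of Star, Cyp11a1, Cyp21a1, Cyp11b1 and Nr5a1 turned when single pools were left out. When adjusted over the list alone, 1 gene passed without hypoxic pool 2, and 1 with the adipose genes' mean as a covariate. Several of these genes were among the brightest measured, and Cyp21a1 in hypoxic pool 3 held the highest value deposited, 30856.6. Whether such bright signals were compressed, which could hide a change, was not tested.

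Genes of cholesterol supply and of the response to ACTH, the pituitary hormone that drives the cortex, also gave few differences. Of 23 measured genes for cholesterol uptake, storage and synthesis, 0 passed over all probe sets and 0 when adjusted over the list alone, and 0 had an unadjusted p under 0.05 in limma at their brightest probe set (camera adjusted p = 0.789). Scarb1, the receptor that takes up cholesterol from high-density lipoprotein, measured 9356 ± 1537 and 9730 ± 1693 (log2 0.05), and its second probe set differed by 0.15. Among the others with the lowest p, Pmvk differed by 0.26, Dhcr7 by 0.16, Msmo1 by -0.20 and Idi1 by -0.21, and a dimmer probe set of Idi1 differed by -0.58 (unadjusted p = 0.00850, adjusted p = 0.352 in limma). Of 19 genes of ACTH and cAMP signalling, 0 passed over all probe sets, 1 passed when adjusted over the list alone, and the list did not move as a group (camera adjusted p = 0.789). That gene was Prkacb, a catalytic subunit of protein kinase A, at 2750 ± 303 and 3759 ± 88.9 (log2 0.45, adjusted p over all probe sets 0.122), and a dimmer probe set of it went the other way (log2 -0.41, adjusted p = 0.881). The inhibin subunit gene Inha had a log2 difference of -0.44, Adcy3 one of -0.31 and Sik1 one of 0.31. Tspo, the translocator protein gene of the outer mitochondrial membrane, differed by 0.13.

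The genes of catecholamine synthesis and chromaffin granules leaned higher in hypoxic glands. All 28 measured genes had a log2 difference above 0, with a median of 0.18, and the list was higher than other genes (camera adjusted p = 3.87e-09); this call was lost at adjusted p = 0.504 with an estimated correlation. In limma 1 of the 28 rose over all probe sets, Slc18a2, and 6 rose when adjusted over the list alone. Besides Slc18a2 these were the neuropeptide gene Npy (log2 0.56, 2117 ± 279 to 3113 ± 238), the secretogranin gene Scg3 (log2 0.59), the noradrenaline-forming enzyme gene Dbh (log2 0.52), the decarboxylase gene Ddc (log2 0.36) and Scg5 (log2 0.33). A dim second probe set of Ddc did not share the difference (log2 -0.06). Th, which makes DOPA at the start of the pathway, measured 8743 ± 1784 and 9573 ± 1939 (log2 0.13), and Pnmt, which makes adrenaline at its end, 9615 ± 1658 and 10270.3 ± 2071 (log2 0.09). Both turned in sign without normoxic pool 1 (log2 -0.0087 for Th and -0.018 for Pnmt). Against the mean change of 10 core chromaffin genes, 0.24, in a test chosen after the data were seen, neither was detectably lower (limma, adjusted p = 0.292 and 0.186). Chga differed by 0.34, Chgb by 0.04, Scg2 by 0.06 and the transcription factor gene Phox2a by 0.00. The beta-actin 5' over 3' ratio, a sign of RNA integrity, was 0.607 ± 0.143 in normoxic and 0.495 ± 0.190 in hypoxic pools (n = 4 each, exact permutation p = 0.4, two-sided), and the Gapdh ratio was 0.665 ± 0.0646 and 0.609 ± 0.0423 (exact permutation p = 0.2).

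Among the genes that respond to low oxygen, those of glycolysis leaned higher. A wider set of genes associated with hypoxia-inducible factors, 23 higher and 15 lower, did not pass as a group. The difference between these lists was not tested. All 13 measured glycolysis genes had a log2 difference above 0, with a median of 0.23 (camera adjusted p = 3.83e-06; adjusted p = 0.437 with an estimated correlation). In limma 0 of them passed over all probe sets and 4 rose when adjusted over the list alone. These were Ldha, which makes lactate, at 3750 ± 256 and 4753 ± 345 (log2 0.34), Aldoa at 8457 ± 1047 and 11073 ± 699 (log2 0.39), Eno1 (log2 0.55) and Pfkp (log2 0.35). Of 38 genes of the hypoxia response, 0 passed over all probe sets and 0 when adjusted over the list alone, 4 having an unadjusted p under 0.05 (camera adjusted p = 0.152). These were the glucose transporter gene Slc2a3 (log2 0.45, with a dim second probe set at -0.23), the collagen cross-linking enzyme gene Lox (0.48), Igfbp3 (0.37) and Ddit4 (-0.36). The angiogenic factor gene Vegfa measured 1340 ± 47.1 and 1512 ± 286 (log2 0.15), and its dimmer probe set differed by -0.31. Slc2a1 differed by -0.09, Hif1a by -0.18 and Epas1 by 0.16, with adjusted p from 0.613 to 0.901, and a dim second probe set of Epas1 differed by -0.14.

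**Figure D2:**
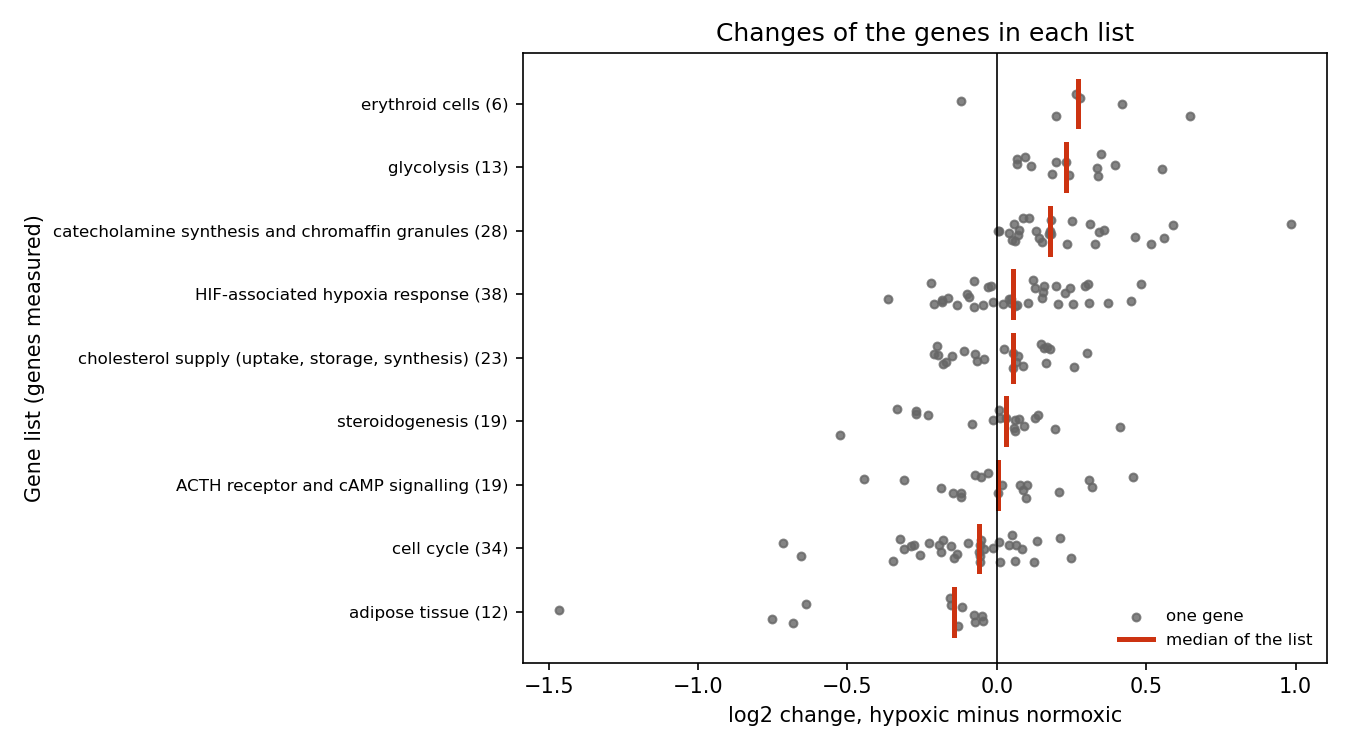
Log2 change (hypoxic minus normoxic, n = 4 pools each) of every measured gene of 9 gene lists; each point is 1 gene and the red bar is the median of the list, with the number of genes in brackets. All 28 chromaffin genes and all 13 glycolysis genes lie above 0, all 12 adipose genes lie below 0, and the steroidogenesis list has a median of 0.03.

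Markers of cells other than those of the inner cortex and medulla were examined because a dissected gland can carry them. The 6 measured erythroid genes had a median log2 difference of 0.27 (camera adjusted p = 0.0228; adjusted p = 0.504 with an estimated correlation). In limma 0 passed over all probe sets and 1 rose when adjusted over the list alone, Alas2, the first enzyme of heme synthesis in red cell precursors (log2 0.42). The anion exchanger gene Slc4a1 had a log2 difference of 0.65 on its brighter and -0.04 on its other probe set, and the haemoglobin gene Hbb one of 0.20. All 12 measured adipose genes were lower in hypoxic pools, with a median log2 difference of -0.14 (camera adjusted p = 0.0489; adjusted p = 0.829 with an estimated correlation), and 0 passed over all probe sets or when adjusted over the list alone, with 2 at an unadjusted p under 0.05 in limma. Ucp1, the uncoupling protein of brown fat, measured 1066 ± 789 in normoxic and 337 ± 176 in hypoxic pools (log2 -1.46, from -1.82 to -0.97 with 1 pool left out, adjusted p = 0.502), and Cidea 1239 ± 852 and 671 ± 276 (log2 -0.68, from -1.05 to -0.31). The erythroid call was lost with the beta-actin ratio as a covariate (adjusted p = 0.217), with that of Gapdh (0.0795), with probe sets averaged per gene (0.0806) and without normoxic pool 2 or 3 or hypoxic pool 1. The adipose call was lost with probe sets averaged (0.0806), with an offset of 1 (0.0513), with the Gapdh covariate (0.139) and without normoxic pool 1 or 4 or hypoxic pool 2 or 4.

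**Figure D3:**
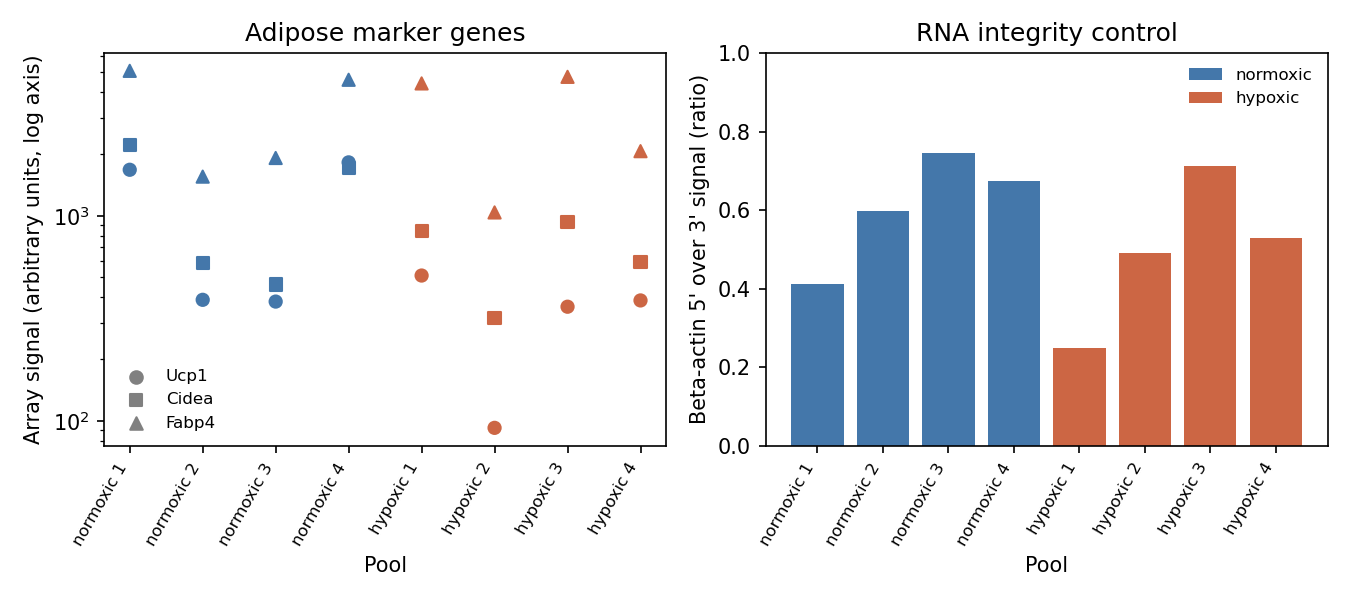
Left, signal of the adipose genes Ucp1, Cidea and Fabp4 in each pool (arbitrary units, log axis); right, the ratio of the beta-actin 5' to the 3' control signal in each pool, with bars from 0. Ucp1 is at 1675 and 1820.3 in normoxic pools 1 and 4 and at 92.3 in hypoxic pool 2, and the actin ratio runs from 0.249 in hypoxic pool 1 to 0.744 in normoxic pool 3.

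Other cell type lists did not pass as groups. Of 15 endothelial genes, 0 passed over all probe sets and 1, Pecam1, fell when adjusted over the list alone (log2 -0.53; camera adjusted p = 0.789). Of 17 leukocyte genes 0 passed in either way, with 3 lower at an unadjusted p under 0.05 in limma, among them the complement genes C1qa (log2 -0.42) and C1qc (log2 -0.34; camera adjusted p = 0.140). Fibroblast and matrix genes (32 measured, adjusted p = 0.140), glomerulosa and capsule genes (16 measured, adjusted p = 0.873), Schwann cell genes (11 measured, adjusted p = 0.789) and kidney and liver genes (6 measured, adjusted p = 0.789) had 0 members past limma over all probe sets or when adjusted over the list alone. Among them Col4a2 differed by 0.38, Dlk1 by 0.23 and Agtr1a by -0.20 (-0.22 on its second probe set), Gfap by -0.36, Serpina1 by 0.44 and Miox by -0.27. The fibroblast list passed as higher without normoxic pool 1 (adjusted p = 0.000172) or 4 or hypoxic pool 2 and with the adipose genes' mean as a covariate (1.65e-09), and turned in direction without normoxic pool 2 (0.962). The leukocyte list passed as lower without hypoxic pool 4 (0.0276).

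Cell cycle genes leaned lower in hypoxic glands. Of 34 measured genes 23 were lower and 11 higher, with a median log2 difference of -0.06 (camera adjusted p = 0.0228; adjusted p = 0.504 with an estimated correlation). In limma 0 passed over all probe sets and 2 fell when adjusted over the list alone, Birc5, the gene of the mitotic protein survivin, from 424 ± 33.6 to 253 ± 33.1 (log2 -0.71, adjusted p over all probe sets 0.0509), and Cdkn3 from 666 ± 108 to 418 ± 73.6 (log2 -0.65). Ube2c differed by -0.31 and the thymidine kinase gene Tk1 by -0.32 on each of its probe sets. The call was lost without normoxic pool 1 (adjusted p = 0.140), without hypoxic pool 2, and with the adipose genes' mean (0.181) or the Gapdh ratio (0.0795) as a covariate.

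The other process lists did not pass as groups, and 0 of their members passed limma over all probe sets. When adjusted over the list alone, Jun was higher (log2 0.32, with 0.24 and 0.12 on its other probe sets) and Junb lower (log2 -0.55) among 18 immediate early genes. The glutathione transferase genes Gsta4 (log2 -0.73) and Gstm2 (log2 -0.43) were lower among 34 antioxidant genes, Igf1r (log2 0.43) was higher among 22 growth factor genes, and the mitochondrial carnitine enzyme gene Cpt2 (log2 0.58) was higher among 32 genes of fatty acid metabolism. In the lists of oxidative phosphorylation (48 genes), heat shock and unfolded protein response (31), glucocorticoid response (20), cytosolic ribosomal proteins (33) and interferon response (17), 0 genes passed when adjusted over the list alone. The camera adjusted p was 0.117 for fatty acid metabolism and for interferon response, 0.140 for heat shock and unfolded protein response, 0.22 for growth factors and 0.374 for ribosomal proteins. It was 0.789 for antioxidant and for glucocorticoid-responsive genes, 0.797 for immediate early genes and 0.961 for oxidative phosphorylation. Within these lists Cox4i2, a subunit of cytochrome oxidase, had a log2 difference of 0.61 and Ndufa5, a subunit of complex I, one of -0.26, the endoplasmic reticulum chaperone genes Hspa5 and Hsp90b1 0.29 and 0.25, Lcn2 0.29 and Ddit4, named above, -0.36, B2m -0.24 and Rps24 -0.21. With the adipose genes' mean as a covariate, chosen after the data were seen, the fatty acid and growth factor lists passed as higher (adjusted p = 0.000308 each). With single pools left out these lists passed as higher without normoxic pool 4, fatty acid metabolism also without normoxic pool 1 or hypoxic pool 2, heat shock as higher without hypoxic pool 2, ribosomal proteins as lower without either pool 1, and interferon response as lower without hypoxic pool 4.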

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

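The tests of the medullary share were chosen only after the result was seen, as were the covariates for RNA integrity and for adipose genes; what those covariates would have to show was fixed before they were fitted.

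Among 196 groups of 4 pools, 17 had a pool that lay apart from the other 3 by more than a test for a single stray value allows, where chance gives about 9.8. In the normoxic group these were Cdh1 in pool 4 (1087, the others 1409 to 1472) and Aox1 in pool 3 (2224, the others 1859 to 1871), both past the threshold as lower in hypoxic glands. In normoxic pool 1 the signals of Star (9378), Tspo (5904) and B2m (7701) lay below the other normoxic pools. In normoxic pool 2 Lox (319.7) and Tk1 (462) lay below and C1qc (502) above. In the hypoxic group Cyp1b1 lay above in pool 2 (8227, the others 7392 to 7490), and Hif1a (1139), Pmvk (179), Cox7a1 (36.7, under the background's 95th percentile of 46.7) and Rpl24 (4060.1) lay below in that pool. Nr5a1 in hypoxic pool 1 stood at 364, the others between 1077 and 1313, and Car2 in that pool stood at 678, above the others. Gstm2 in hypoxic pool 3 (251) and Adcy3 in hypoxic pool 4 (165.5) lay below.

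The first pattern is the 20 probe sets past the threshold. Their median absolute log2 change was 103% of its value (0.80 against 0.78) with the beta-actin ratio as a covariate. It was 97.9% (0.77) with the Gapdh ratio and 100.2% with the adipose genes' mean, and each probe set kept its direction. The slope of a covariate comes from the spread within groups, and these probe sets were picked for a small spread there. Little change was thus likely beforehand, so this does not decide on RNA integrity or fat on the pools. With the Gapdh ratio, though, all 20 calls ended and with the adipose mean 8 stayed, since the median standard error rose from 0.11 to 0.14 and 0.13 while the changes themselves moved little. Chance could not be excluded for the count: 2 of the 35 splits of the 8 arrays into 4 and 4 gave at least 20 calls, the real split included, and the highest of the others gave 45. RNA integrity and fat on the pools stay open. So do an effect of hypoxia itself, of growth or feeding that goes with it, of litters or of the sex of the pups, none of which was tested as a cause. Likewise 0 steroidogenic genes were called in each of the 35 splits, so that count separates nothing.

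The second pattern is the chromaffin gene list, higher in hypoxic glands; with the beta-actin ratio as a covariate its median log2 change was 134% of its value without it (0.24 against 0.18), but with the Gapdh ratio it was 70.3% (0.12), so part of it could stem from RNA integrity, which stays open. A larger share of medulla in hypoxic pools, of unchanged cells, would raise chromaffin genes alike. Of 10 core genes, Slc18a2 left out, 3 departed from their mean of 0.24. These were Npy by 0.32 and Dbh by 0.28 above it, and Phox2a by -0.23 below it (limma, adjusted p = 0.00503, 0.0117 and 0.0431). The test was chosen after the values of these genes were seen, and each departure is taken from a mean that the other genes set. It therefore does not decide on the share of medulla. Chance could not be excluded, since 2 of the 35 splits, the real one included, gave a camera p as small (1.61e-10 against 3.61e-12 in the best other split). Slc18a2 itself exceeded the mean of these genes by 0.75 on the log2 scale, or by 0.37 at its second probe set, but it was taken because it had passed the threshold, so this decides nothing. Expression per chromaffin cell was not measured. A change in it, a larger medulla or both stay open until chromaffin cells are counted beside in situ signals. Compression of bright signals such as those of Th and Pnmt was not tested.

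For glycolysis 1 of 35 splits, the real one, gave a camera p as small (3.19e-07 against 1.30e-05 in the best other split). That is the smallest share 35 splits can give. The 5 lists counted in this way were those called in the real grouping, which favours the real split, and no allowance was made for their number. The list's call was lost at adjusted p = 0.437 with an estimated correlation and at 0.223 by fry. The split count therefore does not exclude chance for glycolysis. For the cell cycle list chance could not be excluded, with 4 of 35 splits as small (0.00306 against 0.000250). It could not be for the erythroid list either, with 7 of 35 splits (0.00380 against 1.01e-06). The count of 5 lists called was reached or passed in 24 of 35 splits, the highest other split calling 13.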

How the results depend on the processing

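The covariates, the fits without both replicate 1 arrays and, for the lists, the subtraction of array medians were chosen only after the data were seen. Each of the 20 called probe sets kept its direction, with an unadjusted p under 0.05, in every limma fit that tested it. The 50th percentile filter tested 19 of them. Their selection largely fixed this beforehand, since they were picked from the same arrays for a small p. Their groups do not overlap, so leaving out pools or changing the offset could not turn a direction. Filter and trend settings leave the changes as they were. The count of calls was free to move. It was 20 with an offset of 1 and with a 1.5-fold threshold, 21 with an offset of 64, with the 50th percentile filter and with quantile normalization, 28 with array weights, and 20 with array medians subtracted, where 15 in place of 13 were higher. It was 0 without the brightness filter (1199 probe sets at an unadjusted p under 0.05), 0 without the variance trend (941) and 0 in an unmoderated two-sample test (942, smallest adjusted p 0.126), 35 at an adjusted p of 0.1, 37 with the beta-actin ratio as a covariate (20 shared), 6 without both replicate 1 arrays (1 shared) 9 with the adipose covariate (8 shared) and 0 with the Gapdh ratio as a covariate (813, smallest adjusted p 0.0981). Leaving out 1 array gave 0 to 31 calls: 31 without hypoxic pool 1, of which 19 were shared, 2 without hypoxic pool 4, 1 without normoxic pool 4 and 0 without each of the others. A fit with 1 array fewer has less residual freedom; otherwise the cause was not tested. Over 18 called named genes, 395 alternative values held 159 on the same side of the threshold, 236 past it no longer and 0 with another sign. The kept sign was likewise largely set by how these genes were selected. In the 18 alternatives run for steroidogenic genes, 0 of them were called over all probe sets. Adjusted over the list alone, 1 was called without hypoxic pool 2 and 1 with the adipose covariate. Dim probe sets limit what can be seen: the filter stood at a signal of 95.2, the background's 95th percentile at 46.7.

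With the replicate number as a replicate block, 18 probe sets were called, 12 of them among the 20, and 5 lists, the same 5. The labels give no pairing of pools by number, and the values leave it open. Deviations from the group mean correlated by 0.32, 0.00, 0.19 and -0.04 between pools of the same number, 2 of the 4 over 0.1, and 4 of 8 arrays correlated best with their own number.

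For the gene lists, 0 passed with an estimated correlation, 0 by fry, 3 with probe sets averaged and 2 with the Gapdh covariate, against 5; leaving out 1 array gave 4 to 7. The adjusted p with an estimated correlation and by fry were 0.504 and 0.259 for the chromaffin list, 0.437 and 0.223 for glycolysis, 0.504 and 0.434 for erythroid genes, 0.829 and 0.952 for adipose genes, and 0.504 and 0.295 for the cell cycle; the estimated correlation between genes is the change that ended these calls in camera. Chromaffin and glycolysis genes passed in every other alternative. Erythroid genes were at 0.0806 with probe sets averaged, 0.217 with the beta-actin and 0.0795 with the Gapdh covariate, 0.105 without both replicate 1 arrays, and 0.00118 to 0.209 with 1 array left out. Adipose genes were at 0.0806 with probe sets averaged, 0.0513 with an offset of 1, 0.139 with the Gapdh covariate, 0.120 without both replicate 1 arrays, and 0.000195 to 0.447 with 1 array left out; the adipose covariate is made of these genes and was not applied to them. Cell cycle genes were at 0.0602 without both replicate 1 arrays, 0.181 with the adipose and 0.0795 with the Gapdh covariate, and 0.00349 to 0.140 with 1 array left out. The cause was not tested.

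Lists that were not called turned direction in 42 of 399 alternative values, and 18 values passed the threshold. Fibroblast and fatty acid genes passed as higher without normoxic pool 1 or 4, without hypoxic pool 2, without both replicate 1 arrays and with the adipose covariate, with lowest adjusted p of 1.65e-09 and 0.000308 under that covariate. Growth factor genes passed as higher without normoxic pool 4 (0.0282) and with the adipose covariate (0.000308). Ribosomal proteins passed as lower without normoxic pool 1, hypoxic pool 1 or both (0.000720). Heat shock genes passed as higher without hypoxic pool 2 (0.0291), leukocyte and interferon genes as lower without hypoxic pool 4 (0.0276 each). With the beta-actin covariate the direction turned for steroidogenesis and endothelial cells (adjusted p = 0.780 each) and for kidney and liver and immediate early genes (0.975 each). With the adipose covariate it turned for glomerulosa and capsule (0.162), glucocorticoid response (0.436), oxidative phosphorylation (0.513) and ribosomal proteins (0.843). With probe sets averaged it turned for ACTH signalling (0.763) and oxidative phosphorylation (0.969), and with array medians subtracted for oxidative phosphorylation (0.826). Without both replicate 1 arrays it turned for endothelial cells (0.727), kidney and liver (0.139), immediate early (0.527) and antioxidant genes (0.80). With 1 array left out the adjusted p of lists that turned ran from 0.318 to 0.986 for steroidogenesis, 0.517 to 0.986 for cholesterol supply, 0.530 to 0.962 for ACTH signalling, 0.296 to 0.876 for glomerulosa and capsule, 0.510 to 0.923 for endothelial cells, 0.238 to 0.962 for kidney and liver and 0.311 to 0.936 for Schwann cells. It ran from 0.000172 to 0.962 for fibroblasts, 0.517 to 0.986 for immediate early genes, 0.484 to 0.995 for glucocorticoid response, 0.182 to 0.962 for oxidative phosphorylation, 0.198 to 0.936 for antioxidant genes and 0.0258 to 0.831 for ribosomal proteins. The cause was not tested.

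Of 76 named genes that were not called, 26 of 1662 alternative values changed sign and 11 passed the threshold. Birc5 passed with array weights (adjusted p = 0.0261), the 50th percentile filter (0.0378), an offset of 64 (0.0491), the beta-actin covariate (0.0373) and without hypoxic pool 1 (0.0442). Eno1 passed with the beta-actin covariate (0.0490) and without hypoxic pool 1 (0.0425), Cpt2 without that pool (0.0425) and without both replicate 1 arrays (0.0435), and Cdkn3 (0.0247) and Npy (0.0363) with the beta-actin covariate. Star was at a log2 change of 0.024 with array medians subtracted, Cyp21a1 at -0.062 with quantile normalization, -0.069 with array weights, -0.010 with the Gapdh covariate and -0.11 without both replicate 1 arrays, Cyp11a1 at -0.025 and Cyp11b1 at -0.10 without both, Nr5a1 at 0.15 with the beta-actin covariate and Scarb1 at -0.018 with the adipose covariate. With 1 array left out the log2 changes ran from -0.12 to 0.055 for Star, -0.0085 to 0.19 for Cyp11a1, -0.098 to 0.24 for Cyp21a1, -0.070 to 0.21 for Cyp11b1, -0.46 to 0.15 for Nr5a1, -0.057 to 0.17 for Scarb1, -0.0087 to 0.26 for Th and -0.018 to 0.19 for Pnmt. The cause was not tested.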

Other observations

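The genes in the next paragraph were chosen after their values were seen, and the tests of fat left on the pools and of the genes behind another split of the arrays were chosen only after those results were seen.

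At an adjusted p of 0.1 in limma, 35 probe sets passed, 23 higher and 12 lower in hypoxic glands. Ass1, an enzyme gene of arginine synthesis, measured 140.1 ± 32.6 in normoxic and 313 ± 73.2 in hypoxic pools (n = 4 pools each, log2 1.07, adjusted p = 0.0725). Nsf, the ATPase that recycles the vesicle fusion machinery, passed on 2 probe sets (log2 0.91 and 0.62, adjusted p = 0.0844 and 0.0800). Map1b, a microtubule protein gene of neurons, was higher by 0.55 (adjusted p = 0.0669), Il18 by 0.66 (adjusted p = 0.0669), Xdh, the xanthine oxidase gene, by 0.64 (adjusted p = 0.0970) and the phosphodiesterase gene Pde10a by 0.84 (adjusted p = 0.0973). Serpini1, the neuroserpin gene, was lower (log2 -0.85, adjusted p = 0.0647), as were Acss2 (log2 -0.59, adjusted p = 0.0844) and Coa7 (log2 -1.12, adjusted p = 0.0796). These pass no stricter threshold and are listed as candidates for measurement.

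The third pattern is fat, where the adipose list, lower in hypoxic pools, had genes that varied together within groups: their mean residual correlation was 0.564, above all 10000 random lists of like brightness (100 as a percentile, highest 0.30); ribosomal proteins reached 0.621 and fibroblast genes 0.526, so the value does not single out fat left on some pools. Of its 12 genes 2, Fabp4 and Lpl, also stand in the fatty acid list, and Fabp4 measured 3288 ± 1815 in normoxic and 3069 ± 1808 in hypoxic pools. The list's median log2 change was 192% of its value with the beta-actin ratio as a covariate and 135% with the Gapdh ratio. The list's call stayed with the beta-actin ratio and was lost with the Gapdh ratio. Since its genes varied together and no error was given for these medians, they do not decide on RNA integrity, which stays open. Chance could not be excluded, with 16 of 35 splits giving a camera p as small (0.0102 against 3.74e-15 in the best other split). Fat left at dissection and an effect of hypoxia on the fat around the gland cannot be told apart here, since genes of any tissue present in varying amounts vary together.

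The split of the arrays with the most calls, 45 against the real 20, set normoxic pools 1 and 4 and hypoxic pools 1 and 3 against the rest. It is no grouping of the study, and these are the 4 pools with the highest adipose mean. The split was picked for its calls, so whether a structure of the pools other than oxygen lies behind it stays open. Of its calls 42 were higher in these 4 pools, H19 by 1.46, Fabp4 by 1.56, Postn by 1.39 and Agtr1b by 0.80 on the log2 scale, and 0 were among the 20 hypoxia calls. Of its 40 genes 13 belonged to the adipose, glomerulosa and capsule or fibroblast lists, where 0.30 would be by chance if genes varied independently. They do not, and the lists were picked after these genes were seen, so whether fat, capsule or connective tissue was left on some pools stays open.

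Xist, which is expressed from the inactive X chromosome of females, ranged from 964 to 5442 over the 8 pools (exact permutation p = 0.457 between groups, two-sided). It stood at 1791.5, 4425, 3269 and 3701 in normoxic pools 1 to 4, and at 5442, 964, 1463 and 1799 in hypoxic pools 1 to 4. The sex of the pups in each pool is not given in the sources used here, so an uneven mix between groups is not excluded. The spike-in controls of hypoxic pool 2 stood at 0.586 of the median of the other arrays.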
